A study of Homo sapiens with 29 samples.

How the data were processed

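Polyadenylated RNA of 29 EndoC-βH1 samples was sequenced after 10 days in conditioned medium. Per the labels' protocols, HEK293 cells that stably overexpressed an empty vector, wild-type CEL or mutant CEL conditioned EndoC-βH1 medium for 3 hours, and the medium was filtered, adjusted to equal protein and renewed daily. Libraries were made with a TruSeq Stranded mRNA kit and sequenced on a NovaSeq instrument with a target of 50 M reads, per the labels' protocols. The mutation carried by the mutant CEL is not named in the sources used here.

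The authors deposited estimated counts per Ensembl gene, with 1 column per library and no normalization. Per the submitters' processing notes the tools were fastp, which trims reads, and kallisto, which assigns reads to transcripts without alignment. Their versions, the genome build, the annotation release and the way transcripts were summed to genes are not given in the sources used here. Kallisto shares reads between similar transcripts by estimation, so genes with near-identical copies are uncertain. Of 22344 entries with at least 5 counts per library, 1054 in 462 sets held the same values as another entry, as the same gene on an alternative sequence would. Counts of genes are counts of entries, such repeats included. The table held 66025 entries, of which 59369 had a symbol, and the rest held 2.69% of the counts. Symbols were matched by Ensembl identifier. Coordinates were taken from GENCODE release 29 (GRCh38) by the same identifier, and the authors' build may differ.

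Totals per library ran from 26.2 to 40.2 M estimated counts. The deposited estimated counts were rounded to whole numbers before testing. Groups and batches came from the sample labels. The label of EV library 2 of batch 1 has a sample number out of sequence with the others, no EV library 1 of that batch was used here, and the library was used as labelled. Low genes were removed with filterByExpr, which left 21259, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in a model with batch and medium over all 29 libraries, which leaves 24 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were scaled by TMM and are given as mean ± SD over libraries. A medium effect that differed between batches was tested as the interaction of medium and batch, and each batch was also fitted alone. The low-count filter was repeated in those fits.

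Before the data were examined, 40 gene lists were fixed, covering β-cell identity and secretion, markers of other pancreatic cells and of HEK293 cells, the unfolded protein response and other stress responses, lipid and energy metabolism, inflammation, the cell cycle and growth signalling. Of these, 39 had at least 5 measured members and were tested with camera at a preset correlation between genes of 0.01, beside camera with an estimated correlation and the rotation test fry, with Benjamini-Hochberg adjustment over the lists. No list passed with an estimated correlation in any comparison. The lists that camera did not call had adjusted p-values from 0.059 to 0.94 for MUT vs EV, 0.061 to 1 for MUT vs WT and 0.086 to 0.89 for WT vs EV.

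The rule for named genes was also fixed before the data were examined. It allowed CEL and INS, per comparison the 6 highest and 6 lowest changes among genes that passed, had a mean of at least 5 CPM and the same sign in every batch alone, up to 4 members with the smallest p from each list that camera called or that had at least 3 passing members, up to 2 from the others, and a short set of β-cell and stress genes. From the genes it allowed, 107 results were picked after their values were seen and examined under the alternatives, 105 to 107 of them in each. Other genes it allowed are not reported here. PDGFD, GPX3, LTK, MC1R, DUSP4 and others named in overlaps between comparisons are members of that set in at least 1 comparison.

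The alternatives fixed before the data were examined were DESeq2 (version 1.42.0), its size factors, total library size as the only scaling, no filter or a stricter filter on low counts (1 CPM in 9 libraries), no batch term, a block of replicate numbers, a fit of only the 2 groups compared, limma voom with quality weights, a test against a fold of 1.2, and leaving out each batch or library. Alternatives added after seeing the data were 1 summed profile per batch and medium, which leaves 4 residual degrees of freedom, a voom fit with the correlation between libraries of a batch and medium estimated, and offsets that removed each library's trend on GC content and gene length. Overlaps between comparisons that share libraries were set against 12 simulations of unchanged groups, in which all 29 libraries were simulated and drawn independently. Figures were drawn with matplotlib 3.10.9.

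The steps were tested on simulated counts with known changes, drawn from the means and totals of these libraries. For a simulated MUT vs EV over 21051 genes, 41.8%, 80.6% and 93.9% of the genes changed by 1.2, 1.5 and 2-fold were recovered, and 5.9% of calls were false. For summed profiles these shares were 26.9%, 74.6% and 90.9%, with simulated libraries that had no spread between batch-and-medium sets. Of 20 random lists, 0 were called by camera at the preset correlation. All simulated counts were drawn independently for each gene and library. The share of false calls and the random lists therefore could not show errors from correlated genes or from spread between batch-and-medium sets.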

Results

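The series measured polyadenylated RNA in EndoC-βH1 cells, a human pancreatic β-cell line that makes and secretes insulin, after 10 days in medium conditioned by HEK293 cells, a human embryonic kidney line. The HEK293 cells carried an empty vector (EV, 9 libraries), wild-type CEL (WT, 10 libraries) or mutant CEL (MUT, 10 libraries). CEL encodes carboxyl ester lipase, a digestive enzyme secreted by pancreatic acinar cells, and mutations in it cause the inherited diabetes MODY8. The labels put the 29 libraries in 3 batches. Batch 1 held 3 EV, 4 WT and 4 MUT libraries, and batches 2 and 3 held 3 of each. Totals ran from 27 to 39.5 M estimated counts in EV libraries, from 26.2 to 38.3 M in WT and from 28.7 to 40.2 M in MUT. The labels do not say whether the libraries of a batch and medium came from separate cultures, so p-values over the 29 libraries measure the spread between these libraries, which may be technical.

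Batch was the main axis of variation. It held 42.5% of the variance of log2 CPM, against 6.39% for medium, 14.7% for medium within batch and 36.4% for libraries of a single batch and medium. These shares rest on 2, 2, 4 and 20 degrees of freedom, and per degree of freedom they were 21.2%, 3.2%, 3.69% and 1.82%. By that measure medium held no more than its variation between batches. The nearest library of every one of the 29 lay in its own batch. For 19 of 29 it also shared the medium, with 9 of 9 in batch 2, 6 of 9 in batch 3 and 4 of 11 in batch 1. The 33 pairs of libraries of one batch and medium held no copies, since they differed by 1.68 to 7.08 times the sampling noise.

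**Figure D1:**
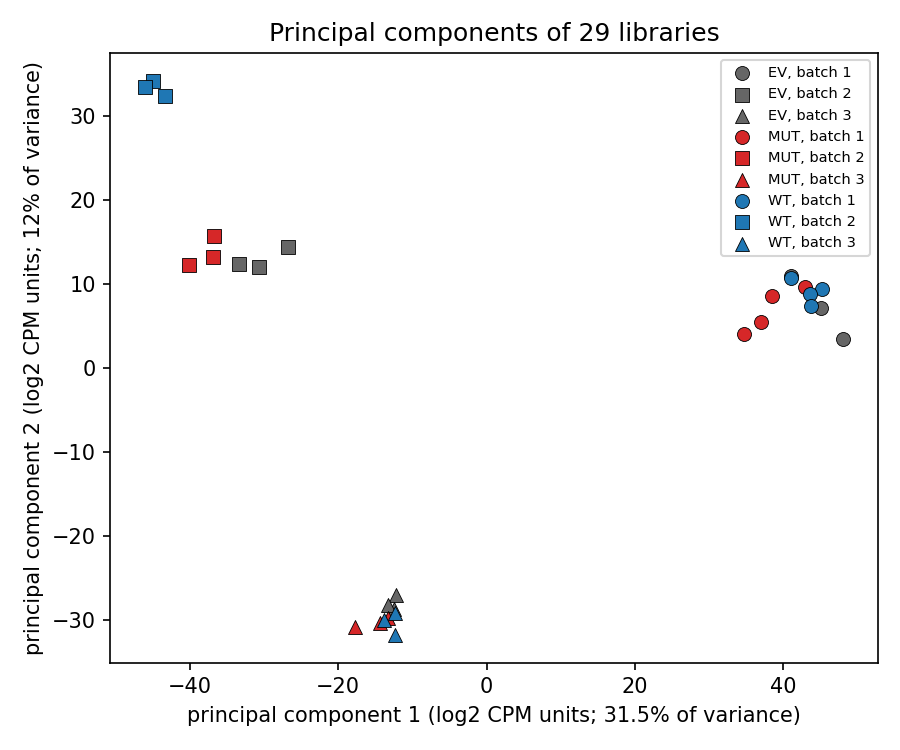
Each point is a library, placed by principal components 1 and 2 of log2 CPM (31.5% and 12.0% of the variance), with the medium as colour and the batch as marker shape. The 3 batches lie apart, and the 3 media lie apart from each other mainly in batch 2.

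The differences between the media varied between the batches. Each medium had 1 set of libraries per batch, so a response to the medium cannot be told apart here from differences between sets. The test of a medium effect that differed between batches passed for 9359 of 21259 genes for MUT vs EV, 6046 for MUT vs WT and 5131 for WT vs EV (edgeR quasi-likelihood F test, adjusted p under 0.05). Fitted alone, batches 1, 2 and 3 gave 294, 9843 and 10 genes for MUT vs EV, 58, 6815 and 248 for MUT vs WT, and 3, 8006 and 2 for WT vs EV. No gene passed in every batch in any comparison with edgeR, while 20, 74 and 71 genes had an unadjusted p under 0.05 in the same direction in all 3 batches, where independent batches would give 95.9, 70.0 and 12.7. Across genes, which are not independent replicates, Pearson's r between the fold changes of different batches was 0.10, -0.19 and -0.072 for MUT vs EV (batches 1 and 2, 1 and 3, 2 and 3), 0.026, 0.0046 and -0.11 for MUT vs WT, and -0.033, 0.01 and -0.033 for WT vs EV. In the text that follows, a log2 fold change is given with its standard error over all 29 libraries with batch in the model, and the values in parentheses after it are those of batches 1, 2 and 3 fitted alone, in that order.

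How many genes passed depended on the unit of replication and on the tool. With the libraries of each batch and medium summed to 1 profile, edgeR called 0 genes in each of the 3 comparisons, with 550, 383 and 327 at an unadjusted p under 0.05 for MUT vs EV, MUT vs WT and WT vs EV. A limma voom fit that estimated the correlation between libraries of a batch and medium, at 0.43, called 1, 2 and 11 genes. Both calls for MUT vs WT and 4 of the 11 for WT vs EV were entries without a symbol, 1 of which had estimated counts that traded with those of HLA-B between libraries. On the single libraries DESeq2 called 2168, 584 and 374, and voom with quality weights 1, 266 and 100 (unadjusted 2512, 3335 and 2139). The 2 voom fits differed in the quality weights as well as in the correlation. How far the correlation lowered the counts therefore cannot be told from them. The pooled calls given next treat the 29 libraries as separate replicates.

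CEL itself (chromosome 9, 133061978 to 133071861, GRCh38) was read at low levels in the EndoC-βH1 cells of every group, at 5.35 ± 4.24 CPM in EV (SD, n = 9), 5.13 ± 3.69 in WT (n = 10) and 4.43 ± 3.17 in MUT (n = 10). Its log2 fold change was 0.10 ± 0.14 (-0.03, 0.48, -0.13) for WT vs EV, with an edgeR adjusted p of 0.83, and -0.15 ± 0.15 (-0.41, 0.22, -0.28) for MUT vs EV, with an adjusted p of 0.55. The batches differed more, with EV means of 2.04 ± 0.487, 3.50 ± 0.568 and 10.5 ± 3.12 CPM for CEL in batches 1, 2 and 3 (SD, n = 3 each). Insulin mRNA (INS, chromosome 11, 2159779 to 2161341) averaged 11900 ± 1540 CPM in EV, 10900 ± 3100 in WT and 12200 ± 4400 in MUT. Its log2 fold change was -0.02 ± 0.10 (-0.09, -0.44, 0.50) for MUT vs EV, 0.13 ± 0.10 (0.02, 0.05, 0.32) for MUT vs WT and -0.15 ± 0.10 (-0.10, -0.49, 0.17) for WT vs EV, and none of these passed in the pooled edgeR fit (adjusted p 0.94, 0.54 and 0.54). INS gained a call under 2 of 48 alternatives for MUT vs EV and under 2 for WT vs EV. In batch 2 it averaged 12400 ± 894 CPM in EV, 8840 ± 313 in WT and 9100 ± 283 in MUT (SD, n = 3 each). In batch 3 it averaged 13000 ± 655, 14600 ± 3390 and 18300 ± 1950 CPM (SD, n = 3 each).

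**Figure D2:**
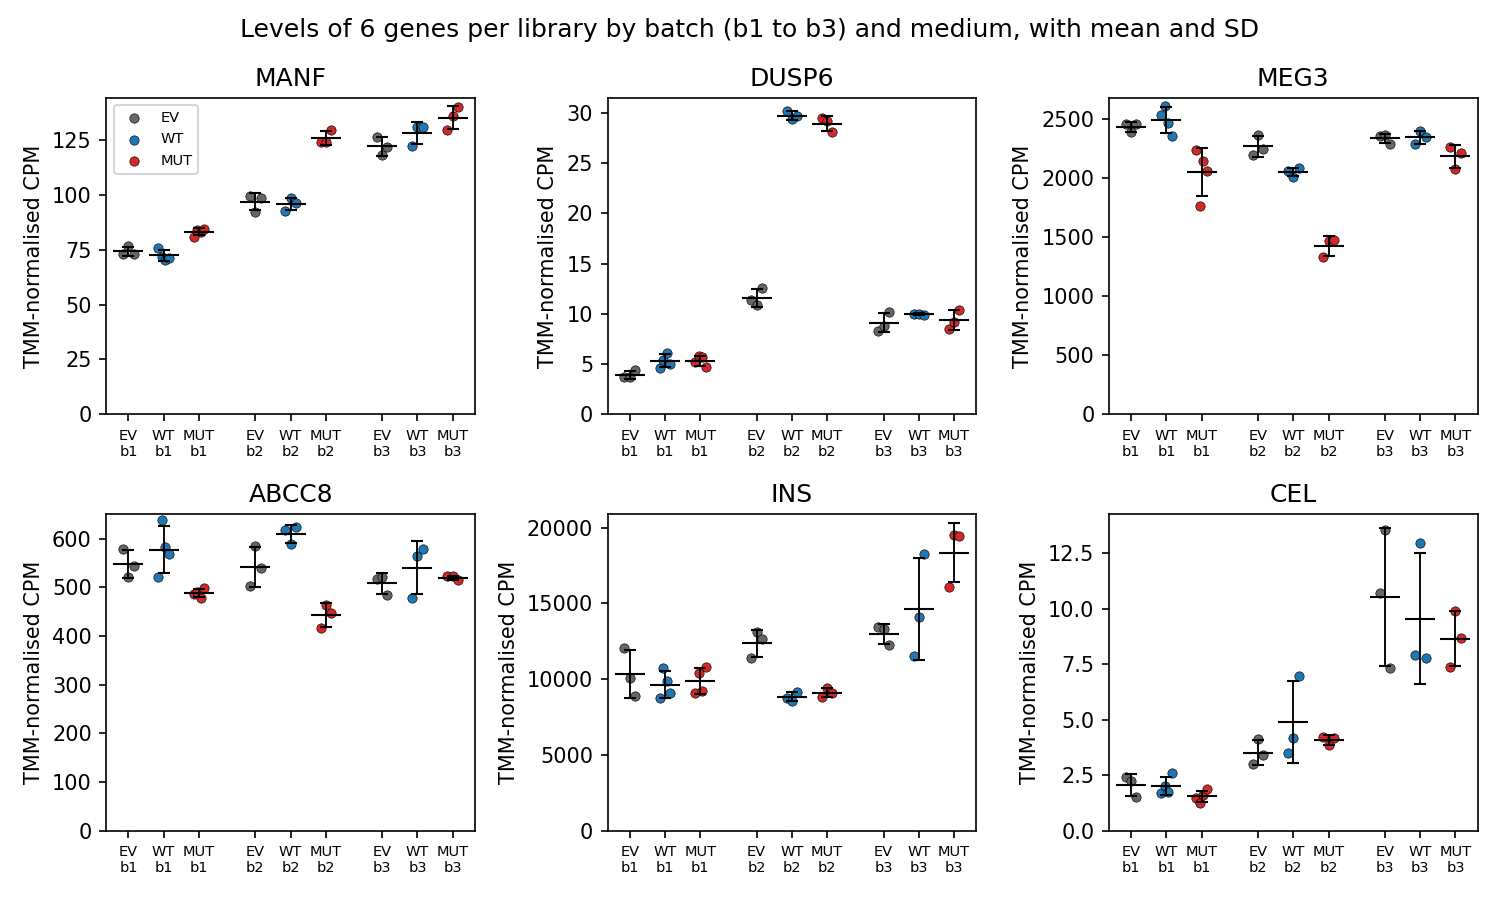
TMM-normalised CPM of 6 genes in each library, by batch and medium, with the mean as a horizontal line and the SD as bars (n = 3, or 4 for WT and MUT in batch 1). MANF is higher and MEG3 lower in MUT than in EV in each batch, DUSP6 is 11.6 CPM in EV and 28.9 in MUT on average in batch 2, and ABCC8, INS and CEL are drawn for comparison.

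MUT against EV compared β cells kept in medium from mutant CEL cells with those kept in control medium. MANF, a secreted folding stress factor (chromosome 3, 51385047 to 51389397), averaged 112 ± 25 CPM in MUT (n = 10) and 97.7 ± 21 in EV (SD, n = 9) and rose by 0.23 ± 0.04 (0.14, 0.38, 0.15), with an edgeR adjusted p of 0.0082. HSPA5, which encodes the chaperone BiP, rose by 0.15 ± 0.03 (0.21, 0.19, 0.01). MEG3, a long noncoding RNA (chromosome 14, 100779410 to 100861031), fell by 0.33 ± 0.06 (-0.26, -0.66, -0.10), from 2350 ± 89.4 to 1900 ± 359 CPM, with an adjusted p of 0.0082. The ERK phosphatase gene DUSP6 (chromosome 12, 89347232 to 89353271) rose by 0.60 ± 0.13 (0.41, 1.32, 0.04), mostly through batch 2.

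In all, 1106 of 21259 genes passed for MUT vs EV, 628 higher and 478 lower, of which 83 changed by over 1.5-fold. With total library size as the only scaling, 443 were higher and 515 lower. The direction was shared by all 3 batches for 59.5% of the 1106 genes and for 17.1% of all genes, where independent signs would give at most 25%. Genes filtered out of a batch counted as not sharing it, here and in the other comparisons. Only 19731 genes were fitted in all 3 batches, so a part of the shortfall comes from the filter. Among the 1106, 845 also passed the test of a change that differed between batches. Leaving out batch 2 left 0 genes with edgeR, with 1916 at an unadjusted p under 0.05, and leaving out batch 3 gave 4744. Omitting EV library 2 of batch 2 left 5 genes and omitting MUT library 3 of batch 3 gave 1999, among 10 libraries that moved the count by over 1.5 times.

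Of the 28 measured endoplasmic reticulum chaperone genes of the ATF6 and IRE1 arms, 7 rose for MUT vs EV over all genes, and 16 rose and 1 fell adjusted over the list alone. They included HYOU1, whose counts are repeated in full by another entry, by 0.18 ± 0.04 (0.08, 0.37, 0.08) and the translocon gene SSR1 by 0.19 ± 0.05 (0.24, 0.39, -0.10). The list median was 0.10, with 0.134, 0.195 and -0.03 in batches 1, 2 and 3. For that list camera gave adjusted p = 1.5e-07, and adjusted p = 0.28 with an estimated correlation. Of 25 genes of endoplasmic reticulum-associated degradation 5 rose, and 8 adjusted over the list alone, among them HERPUD1 by 0.17 ± 0.04 (0.13, 0.29, 0.06), SEL1L by 0.17 ± 0.04 (0.17, 0.34, -0.03), SELENOK by 0.15 ± 0.03 (0.03, 0.25, 0.16) and FAF2 by 0.11 ± 0.03 (0.13, 0.17, 0.02). Their median was 0.06. The list had a camera adjusted p = 0.00068, and adjusted p = 0.24 with an estimated correlation. Of 25 genes of the PERK and ATF4 arm only ASNS, which makes asparagine, rose over all genes, by 0.13 ± 0.04 (0.05, 0.27, 0.05), and 2 rose adjusted over the list alone. Tested with camera, the list had adjusted p = 0.041, and adjusted p = 0.75 with an estimated correlation. Its medians were -0.063, 0.293 and 0.034 in the 3 batches. DDIT3 was at 0.00 ± 0.07 (-0.16, 0.12, 0.03) and ATF4 at 0.04 ± 0.04 (-0.08, 0.17, 0.01), and neither passed.

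Of 35 β-cell identity genes 8 rose and 1 fell for MUT vs EV, and 16 rose and 1 fell adjusted over the list alone (median 0.11, camera adjusted p = 0.00070, and adjusted p = 0.36 with an estimated correlation). The median was 0.052, 0.189 and -0.008 in batches 1, 2 and 3. The transcription factor gene NEUROD1 rose by 0.22 ± 0.05 (0.17, 0.51, -0.04), as did the membrane protein gene TSPAN7, by 0.14 ± 0.03 (0.09, 0.19, 0.14), and the prohormone convertase gene PCSK2, by 0.15 ± 0.04 (0.07, 0.25, 0.11). MEG3 was the member that fell. PDX1 at -0.04 ± 0.06 (0.09, -0.17, -0.11), MAFA at -0.10 ± 0.08 (0.04, -0.44, 0.01), NKX6-1 at -0.04 ± 0.05 (-0.02, -0.15, 0.01) and the glucose transporter gene SLC2A2 at -0.23 ± 0.11 (-0.04, -0.68, -0.11) did not pass in the pooled fit. Each gained its call under 1 of 48 alternatives. In batch 2 alone 18 members of the list were higher and 7 lower, and these genes all lay lower. There PDX1 was at 441 ± 14.5 CPM in EV and 392 ± 8.28 in MUT, and MAFA at 143 ± 5.51 and 105 ± 6.48 (SD, n = 3 each). The somatostatin gene SST rose by 0.36 ± 0.09 (0.26, 0.16, 0.59), 1 of 13 genes of other islet hormones and their regulators to pass, and 2 rose adjusted over the list alone. Camera on this list gave adjusted p = 0.54, and adjusted p = 0.79 with an estimated correlation.

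Of 24 immediate early genes, which follow growth factor and calcium signals, 5 rose for MUT vs EV and 15 adjusted over the list alone (median 0.38, camera adjusted p = 4.6e-08, and adjusted p = 0.35 with an estimated correlation). Their median was 0.925 in batch 2 and -0.003 and 0.052 in batches 1 and 3. DUSP5 rose by 0.56 ± 0.14 (0.18, 1.41, 0.21) and DUSP4 by 0.38 ± 0.08 (0.31, 0.76, 0.04). Of 12 TGF-β and Hippo targets, TGFB1 rose by 0.42 ± 0.11 (-0.02, 1.01, 0.24) and SMAD7 by 0.34 ± 0.09 (0.30, 0.83, -0.13), and 6 rose adjusted over the list alone. For that list camera gave adjusted p = 0.0090, and adjusted p = 0.36 with an estimated correlation. The list medians were -0.038, 0.706 and -0.065 in the 3 batches, so the median lay above 0 in batch 2 alone. The list of 20 p53 targets had 3 higher and 1 lower, and 4 higher and 1 lower adjusted over the list alone, with TP53INP1 at 0.30 ± 0.08 (0.10, 0.88, -0.07) and DDB2 at -0.22 ± 0.06 (-0.20, -0.46, 0.04; camera adjusted p = 0.034, and adjusted p = 0.36 with an estimated correlation). The p53 list had medians of -0.024, 0.326 and 0.029 in the 3 batches. Of 29 apoptosis regulators the proapoptotic BID, by 0.19 ± 0.05 (-0.01, 0.40, 0.19), and the antiapoptotic MCL1, by 0.16 ± 0.05 (0.20, 0.34, -0.11), rose, and 5 adjusted over the list alone. The list had a camera adjusted p = 0.041, and adjusted p = 0.24 with an estimated correlation.

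Single genes rose in several metabolic lists. The autophagy genes MAP1LC3B, by 0.14 ± 0.03 (0.16, 0.19, 0.05), and WIPI2, by 0.12 ± 0.03 (0.06, 0.25, 0.02), were 2 of 34 members, over all genes and adjusted over the list alone. Tested with camera, the list had adjusted p = 0.0090, and adjusted p = 0.42 with an estimated correlation. The cholesterol synthesis gene DHCR7, by 0.15 ± 0.04 (0.03, 0.35, 0.06), was 1 of 26, with 5 higher and 1 lower adjusted over the list alone. Camera on this list gave adjusted p = 0.034, and adjusted p = 0.44 with an estimated correlation. SMPDL3A, by 0.22 ± 0.06 (0.12, 0.52, 0.00), was 1 of 12 sterol efflux genes and SOX4, by 0.31 ± 0.09 (0.27, 0.69, -0.05), 1 of 12 progenitor markers, with 3 and 4 higher adjusted over the list alone (camera adjusted p = 0.019 and 0.018, and adjusted p = 0.35 and 0.34 with an estimated correlation). In the 3 batches the medians were 0.031, 0.26 and 0.07 for sterol efflux genes and 0.043, 0.404 and -0.059 for progenitor markers. The antioxidant genes GPX2, by 1.05 ± 0.21 (0.08, 2.22, 0.57), and SRXN1, by 0.30 ± 0.07 (0.16, 0.77, 0.00), were among 4 of 26 NRF2 and oxidative stress genes that rose, with 6 higher and 2 lower adjusted over the list alone. For that list camera gave adjusted p = 0.13, and adjusted p = 0.36 with an estimated correlation. GPX2 was the only gene that the voom fit with correlated libraries called. Of 42 cell cycle genes the replication helicase genes MCM7, by -0.23 ± 0.07 (-0.09, -0.62, 0.03), and MCM5, by -0.24 ± 0.07 (-0.11, -0.72, 0.10), fell. Adjusted over the list alone, 1 was higher and 7 lower, at medians of 0.056, -0.137 and 0.023 in the 3 batches. Camera called the list higher in batch 1 alone (adjusted p = 0.00061) and lower in batch 2 alone (adjusted p = 1.7e-08). The pooled list had a camera adjusted p = 0.091, and adjusted p = 0.81 with an estimated correlation. None of 25 interferon-stimulated genes passed in either adjustment with edgeR, at a median of -0.17, with 0.011, -0.378 and 0.065 in batches 1, 2 and 3. Tested with camera, the list had adjusted p = 0.041, and adjusted p = 0.75 with an estimated correlation. In all, camera called 13 of 39 lists for MUT vs EV, fry called 13, and camera with an estimated correlation called 0, with 5 at an unadjusted p under 0.05. Of the 13 that camera called at the preset correlation, 3 had medians in the called direction in all 3 batches.

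Some genes with large pooled changes and the same sign in every batch changed most in batch 2. MARCHF4 rose by 0.63 ± 0.17 (0.16, 1.79, 0.03), LRATD1 by 0.46 ± 0.11 (0.13, 1.26, 0.04) and DAB1 by 0.43 ± 0.09 (0.39, 0.81, 0.03). The transporter gene SLC47A1, at -0.87 ± 0.25 (-0.27, -2.67, -0.09), the vitamin C transporter gene SLC23A1, at -0.63 ± 0.14 (-0.35, -1.55, -0.05), and FTCD, at -0.57 ± 0.12 (-0.35, -1.28, -0.15), fell. The share of counts in mitochondrial genes was 7.69% ± 0.603 in EV and 6.20% ± 0.311 in MUT in batch 1 (SD, n = 3 and 4), 5.03% ± 0.227 and 5.07% ± 0.299 in batch 2, and 4.43% ± 0.185 and 4.76% ± 0.279 in batch 3 (n = 3 each). Fold changes for MUT vs EV followed the GC content of the genes with a Spearman's rho of -0.42, -0.11 and 0.35 across genes in batches 1, 2 and 3.

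**Figure D3:**
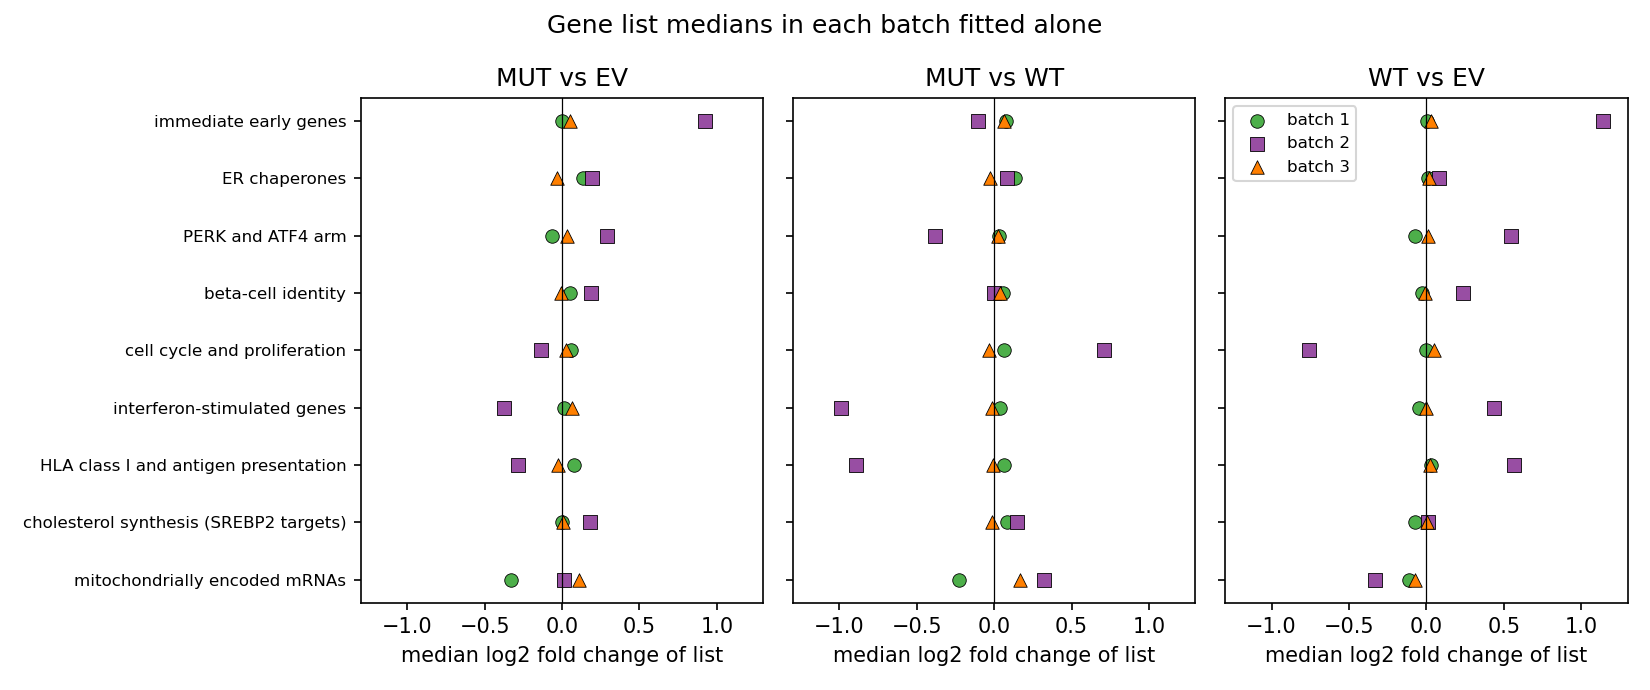
Median log2 fold change of 9 gene lists in each batch fitted alone, for the 3 comparisons, with a marker for each batch and a line at 0. Batch 2 gives medians of 0.925 for immediate early genes for MUT vs EV and -0.992 for interferon-stimulated genes for MUT vs WT, where batches 1 and 3 give -0.003 and 0.052, and 0.037 and -0.012.

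MUT against WT compared β cells kept in medium from mutant CEL cells with those kept in medium from cells overexpressing normal CEL. MANF rose by 0.22 ± 0.04 (0.18, 0.40, 0.07), from 96.1 ± 24.5 CPM in WT to 112 ± 25 in MUT (SD, n = 10 each), with an edgeR adjusted p of 0.0017. ABCC8, which encodes the sulfonylurea receptor of the β-cell potassium channel (chromosome 11, 17392498 to 17476879), fell by 0.25 ± 0.05 (-0.26, -0.46, -0.06), from 577 ± 48.5 to 485 ± 34.1 CPM, with an adjusted p of 0.0091. The calcium channel gene CACNA1A fell by 0.35 ± 0.05 (-0.33, -0.52, -0.22) and MEG3 by 0.30 ± 0.06 (-0.30, -0.52, -0.11). CBLN2, a secreted synaptic organiser, rose by 0.57 ± 0.09 (0.34, 1.12, 0.29), and ARSL by 0.42 ± 0.06 (0.23, 0.73, 0.35).

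In all, 188 genes passed for MUT vs WT, 111 higher and 77 lower, of which 18 changed by over 1.5-fold, and 93.1% of the 188 kept their direction in all 3 batches, as did 19.3% of all genes, where independent signs would give at most 25%. Genes that pass a pooled fit are picked in part for a common direction. Of 170 genes called in batch 2 alone and in batch 3 alone, 19 changed in the same direction and 151 in opposite directions. Independent calls would give 40.9 in opposite directions. Of 28 genes called in batches 1 and 2, 15 changed in the same direction and 13 in opposite directions, and batches 1 and 3 shared 0. With total library size as the only scaling, 65 were higher and 97 lower. Of the 188, 67 also passed the test of a change that differed between batches. Leaving out batch 1, 2 or 3 gave 104, 305 and 1552 genes. Omitting MUT library 1 of batch 2 left 63, the lowest of 8 libraries that moved the count by over 1.5 times.

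Several genes of lipid metabolism rose in MUT against WT. Of 21 genes of fatty acid and triglyceride synthesis the desaturase genes FADS1, by 0.14 ± 0.03 (0.14, 0.20, 0.05), FADS2, by 0.19 ± 0.05 (0.15, 0.16, 0.24), and SCD5, by 0.24 ± 0.06 (0.11, 0.54, 0.06), rose over all genes and adjusted over the list alone (median 0.05, camera adjusted p = 0.0071, and adjusted p = 0.27 with an estimated correlation). Of 26 cholesterol synthesis genes DHCR7 rose by 0.19 ± 0.04 (0.19, 0.31, 0.02), and 13 rose adjusted over the list alone (medians of 0.083, 0.15 and -0.017 in the 3 batches, camera adjusted p = 2e-07, and adjusted p = 0.27 with an estimated correlation). LPCAT3, a phospholipid acyltransferase, rose by 0.15 ± 0.03 (0.11, 0.14, 0.20), 1 of 12 sterol efflux and LXR targets, with 3 adjusted over the list alone. Camera on this list gave adjusted p = 0.0058, and adjusted p = 0.27 with an estimated correlation. The lysosomal cholesterol carrier gene NPC2 rose by 0.19 ± 0.04 (0.14, 0.30, 0.13), 1 of 34 autophagy and lysosome genes, with 4 adjusted over the list alone. For that list camera gave adjusted p = 0.019, and adjusted p = 0.51 with an estimated correlation. GPX3, a secreted glutathione peroxidase, rose by 0.34 ± 0.07 (0.15, 0.57, 0.32), 1 of 26 NRF2 and oxidative stress genes, with 6 adjusted over the list alone. The list had a camera adjusted p = 0.012, and adjusted p = 0.27 with an estimated correlation.

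Of 28 endoplasmic reticulum chaperone genes MANF rose for MUT vs WT, and 8 adjusted over the list alone, while HSPA5 was at 0.12 ± 0.03 (0.19, 0.15, -0.04) with an adjusted p of 0.056 (list medians 0.133, 0.084 and -0.025 in the 3 batches, camera adjusted p = 3e-06, and adjusted p = 0.27 with an estimated correlation). Of 35 genes of insulin exocytosis and excitability, ABCC8 and CACNA1A fell, and 1 rose and 5 fell adjusted over the list alone (medians of -0.006, -0.13 and -0.01 in the 3 batches, camera adjusted p = 0.0058, and adjusted p = 0.36 with an estimated correlation). The same list was called higher for WT vs EV, at medians of 0.005, 0.209 and -0.004. Camera there gave adjusted p = 0.00026, and adjusted p = 0.28 with an estimated correlation. For MUT vs EV its median was -0.002, with camera adjusted p = 0.57, and adjusted p = 0.82 with an estimated correlation. Of 42 cell cycle genes the mitotic kinase gene AURKA rose by 0.29 ± 0.06 (0.17, 0.76, -0.02), and 13 rose adjusted over the list alone, at medians of 0.064, 0.712 and -0.034 in the 3 batches. Tested with camera, the list had adjusted p = 4.4e-11, and adjusted p = 0.33 with an estimated correlation. Of 15 genes of HLA class I and antigen presentation their regulator NLRC5 fell by 0.43 ± 0.08 (-0.26, -0.89, -0.21), with 1 higher and 7 lower adjusted over the list alone. The list medians were 0.065, -0.89 and -0.008 in the 3 batches, and camera gave adjusted p = 0.0024, and adjusted p = 0.32 with an estimated correlation. This list includes HLA-B, whose estimated counts traded with those of an entry without a symbol, so its level is uncertain. No interferon-stimulated gene of 25 passed over all genes with edgeR, and 11 fell adjusted over the list alone, at medians of 0.037, -0.992 and -0.012 in the 3 batches. For that list camera gave adjusted p = 1.8e-08, and adjusted p = 0.27 with an estimated correlation.

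The progenitor markers CD9, by 0.26 ± 0.05 (0.18, 0.43, 0.17), and CD24, by 0.15 ± 0.04 (0.16, 0.28, -0.02), were 2 of 12 that rose for MUT vs WT, with 4 adjusted over the list alone. The list had a camera adjusted p = 0.022, and adjusted p = 0.32 with an estimated correlation. LDHA, by 0.31 ± 0.07 (0.15, 0.61, 0.20) and with counts repeated in full by another entry, and the catalase gene CAT, by 0.12 ± 0.03 (0.10, 0.12, 0.13), were 2 of 14 genes normally kept low in β cells that rose, with 2 higher and 2 lower adjusted over the list alone. Tested with camera, the list had adjusted p = 0.82, and adjusted p = 0.87 with an estimated correlation. The 50 ribosomal protein genes had medians of -0.004, 0.15 and 0.019 in the 3 batches, with 5 higher adjusted over the list alone. Their camera adjusted p was 2e-07, and adjusted p = 0.45 with an estimated correlation. The 13 mitochondrially encoded mRNAs had medians of -0.226, 0.323 and 0.167, with camera adjusted p = 0.043, and adjusted p = 0.71 with an estimated correlation. Fold changes for MUT vs WT followed the GC content of the genes with a Spearman's rho of -0.24, -0.34 and 0.40 across genes in batches 1, 2 and 3. Camera also called proteasome subunits, nuclear-encoded oxidative phosphorylation and endoplasmic reticulum-associated degradation higher (adjusted p = 0.022, 0.031 and 0.031, and adjusted p = 0.46, 0.58 and 0.36 with an estimated correlation). It called the PERK and ATF4 arm and NF-κB targets lower (adjusted p = 0.0039 and 0.0065, and adjusted p = 0.58 and 0.36 with an estimated correlation). Their medians were 0.031, -0.384 and 0.026, and 0.016, -0.469 and 0.12, in the 3 batches, so both medians lay below 0 in batch 2 alone. In all, camera called 18 of 39 lists, 13 higher and 5 lower, fry called 5, and camera with an estimated correlation called 0, with 6 at an unadjusted p under 0.05. Of the 18, 6 had medians in the called direction in all 3 batches.

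WT against EV compared β cells kept in medium from cells overexpressing normal CEL with those kept in control medium. The phosphatase genes DUSP4, at 0.56 ± 0.08 (0.43, 0.87, 0.40; edgeR adjusted p 0.0015), and DUSP6, at 0.64 ± 0.13 (0.43, 1.36, 0.14), and the transcription factor gene ETV5, at 0.57 ± 0.12 (0.22, 1.37, 0.13), rose. SLC30A8, the zinc transporter gene of insulin granules, rose by 0.30 ± 0.06 (0.43, 0.34, 0.14), from 487 ± 112 CPM in EV (SD, n = 9) to 579 ± 101 in WT (n = 10). The chemokine gene CXCL12 rose by 0.50 ± 0.11 (0.11, 0.99, 0.40). The surface protein gene MSLN fell by 0.57 ± 0.09 (-0.39, -0.55, -0.78), with an adjusted p of 0.0036, and the acinar protease gene CPA1 fell by 0.22 ± 0.04 (-0.25, -0.28, -0.14).

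In all, 67 genes passed for WT vs EV, 36 higher and 31 lower, of which 17 changed by over 1.5-fold, and 97.0% of the 67 kept their direction in all 3 batches, as did 21.8% of all genes, where independent signs would give at most 25%. With total library size as the only scaling, 49 were higher and 26 lower. Of the 67, 31 also passed the test of a change that differed between batches. DUSP6, DUSP4, ETV5 and LHFPL6, at 0.50 ± 0.09 (0.37, 0.98, 0.15), were among the 11 genes called by the voom fit with correlated libraries. Leaving out batch 3 gave 551 genes, and omitting EV library 2 of batch 2 left 19, the lowest of 10 libraries that moved the count by over 1.5 times.

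Of 24 immediate early genes 3 rose for WT vs EV and 14 adjusted over the list alone, at medians of 0.005, 1.142 and 0.028 in the 3 batches. Camera on this list gave adjusted p = 8.2e-12, and adjusted p = 0.26 with an estimated correlation. No gene of 42 of the cell cycle passed over all genes with edgeR, and 21 fell adjusted over the list alone, at medians of -0.003, -0.756 and 0.048. For that list camera gave adjusted p = 1.9e-20, and adjusted p = 0.26 with an estimated correlation. Of 25 genes of the PERK and ATF4 arm the cystine transporter gene SLC7A11 rose, by 0.63 ± 0.15 (0.14, 1.42, 0.34), and 7 adjusted over the list alone, at medians of -0.07, 0.546 and 0.008. The list had a camera adjusted p = 1.7e-09, and adjusted p = 0.30 with an estimated correlation. The 13 mitochondrially encoded mRNAs had a median of -0.14, with -0.11, -0.33 and -0.075 in the 3 batches and no member passing in either adjustment with edgeR. Tested with camera, the list had adjusted p = 2.8e-06, and adjusted p = 0.34 with an estimated correlation. The share of counts in mitochondrial genes was 7.21% ± 0.283, 4.01% ± 0.0338 and 4.20% ± 0.516 in the WT libraries of batches 1, 2 and 3. Of 35 β-cell identity genes SLC30A8 rose, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.34 with an estimated correlation), while UCN3 was at 0.30 ± 0.07 (0.07, 0.74, 0.10) with an adjusted p of 0.066. The medians of the identity genes were -0.031, 0.236 and -0.008, so the median lay above 0 in batch 2 alone. HSPA5 was at 0.03 ± 0.03 (0.02, 0.04, 0.04), and of 28 chaperone genes none passed in either adjustment with edgeR. Camera on this list gave adjusted p = 0.092, and adjusted p = 0.75 with an estimated correlation. The 50 ribosomal protein genes had medians of 0.001, -0.162 and 0.055, with camera adjusted p = 0.00082, and adjusted p = 0.72 with an estimated correlation. Fold changes for WT vs EV followed GC content with a Spearman's rho of -0.28, 0.16 and -0.13 across genes in batches 1, 2 and 3. The 29 apoptosis regulators had medians of 0.056, 0.077 and 0.047 and 3 higher adjusted over the list alone, with camera adjusted p = 0.0076, and adjusted p = 0.087 with an estimated correlation. They were the list that fry called, at adjusted p = 0.0041. The 25 interferon-stimulated genes, with medians of -0.045, 0.439 and -0.002, were called higher (camera adjusted p = 0.0068, and adjusted p = 0.61 with an estimated correlation). The 26 cholesterol synthesis genes, with medians of -0.073, 0.011 and 0.003, were called lower (camera adjusted p = 0.040, and adjusted p = 0.58 with an estimated correlation). Camera also called p53 targets, TGF-β and Hippo targets, endoplasmic reticulum-associated degradation and other islet hormones higher (adjusted p = 0.0060, 0.0080, 0.037 and 0.040, and adjusted p = 0.26, 0.34, 0.34 and 0.34 with an estimated correlation). It called glycolysis lower (adjusted p = 0.030, and adjusted p = 0.58 with an estimated correlation). In batches 1, 2 and 3 the medians were 0.03, 0.212 and 0.045 for p53 targets and -0.074, 0.498 and -0.051 for TGF-β and Hippo targets. They were 0.016, 0.085 and -0.003 for endoplasmic reticulum-associated degradation, -0.081, 0.268 and -0.028 for other islet hormones, and -0.038, -0.114 and 0.004 for glycolysis. In all, camera called 16 of 39 lists, 11 higher and 5 lower, fry called 1, and camera with an estimated correlation called 0, with 6 at an unadjusted p under 0.05. Of the 16, 5 had medians in the called direction in all 3 batches.

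Markers of other cells were few. Of 6 measured acinar genes CPA1 fell for WT vs EV, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.48, and adjusted p = 0.75 with an estimated correlation). Of 11 mesenchymal and stellate markers FN1 rose for MUT vs WT by 0.41 ± 0.10 (0.30, 1.04, 0.03), with 2 adjusted over the list alone (camera adjusted p = 0.27, and adjusted p = 0.63 with an estimated correlation). In batch 1 alone camera called this list lower for MUT vs EV and WT vs EV, at medians of -0.256 and -0.21 (adjusted p = 0.031 and 0.0055). The pooled fits gave camera adjusted p = 0.74 and 0.54 for these 2 comparisons, and adjusted p = 0.83 and 0.75 with an estimated correlation. None of 10 ductal markers passed over all genes for MUT vs EV with edgeR, and 2 fell adjusted over the list alone (camera adjusted p = 0.45, and adjusted p = 0.75 with an estimated correlation). For MUT vs WT camera called the ductal list lower in batch 2 alone (adjusted p = 0.033), at medians of 0.006, -0.123 and 0.098 in the 3 batches. The pooled fit there gave camera adjusted p = 0.82, and adjusted p = 0.89 with an estimated correlation. Of 6 HEK293 markers LHX1 rose for MUT vs EV, from 0.171 ± 0.147 CPM in EV (SD, n = 9) to 0.588 ± 0.65 in MUT (n = 10), and 3 rose adjusted over the list alone (camera adjusted p = 0.059, and adjusted p = 0.30 with an estimated correlation). The median of these markers was -0.03, 0.751 and -0.109 in batches 1, 2 and 3. For WT vs EV none of the 6 passed over all genes with edgeR and 1 rose adjusted over the list alone, at medians of 0.029, 0.331 and 0.054. Camera called the list higher there at adjusted p = 0.037, and adjusted p = 0.26 with an estimated correlation. For MUT vs WT camera gave adjusted p = 0.82, and adjusted p = 0.89 with an estimated correlation. The 3 measured endothelial and immune markers were too few to test and had a median of -0.09 for MUT vs EV, with 0.008, -0.448 and 0.2 in batches 1, 2 and 3 and 1 lower adjusted over the list alone.

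MUT differed from both other media in 62 genes, 29 higher and 33 lower, of which 2 of the lower repeat the counts of another, and 55 of the 62 kept their direction in all 3 batches of both comparisons. They included MANF, GPX3, DHCR7 and the growth factor gene PDGFD, which rose by 0.41 ± 0.08 (0.31, 0.61, 0.28) for MUT vs WT, and MEG3 and the receptor kinase gene LTK, at -0.33 ± 0.08 (-0.29, -0.40, -0.34) for MUT vs WT, which fell. The melanocortin receptor gene MC1R also fell, by 0.37 ± 0.07 (-0.33, -0.72, -0.12) for MUT vs WT, but was among the 7 that did not keep their direction, through batch 3 of MUT vs EV. Independent lists would share 3.3 higher and 1.7 lower genes. The 2 comparisons share the MUT libraries, and their fold changes had a Pearson's r of 0.52 across genes, where 12 simulations without any effect gave 0.49 on average, and a covariance of 0.02 against 0.017. Without batch 2, 0 genes passed both tests with edgeR, where MUT vs EV alone had 1916 at an unadjusted p under 0.05, and without batch 3, 1054 did. Omitting EV library 2 or 3 or MUT library 1 of batch 2 left 2 genes, among 16 libraries that moved the count by over 1.5 times.

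MUT and WT were compared with the same EV libraries, so their changes against EV are not independent. In 18 genes both passed in the same direction, 10 higher and 8 lower, where independent lists would share 1.1 and 0.7. DUSP6, DUSP4 and DAB1 were among the higher genes, and ITPKA, at -0.46 ± 0.10 (-0.39, -0.54, -0.43) for WT vs EV, PADI2, at -0.53 ± 0.11 (-0.18, -1.0, -0.43), and ST3GAL1, at -0.39 ± 0.08 (-0.32, -0.57, -0.25), among the lower. The fold changes had a Pearson's r of 0.56 across genes and a covariance of 0.023. In 12 simulations of unchanged groups, with the shared EV libraries simulated too, r was 0.52 on average and 0.45 to 0.56, and the covariance 0.018. Simulated libraries were drawn independently, without the likeness of libraries of a batch and medium. With the measured EV libraries split into parts of 4 and 5, each comparison against its own part, r was 0.18 and 0.14. In these splits edgeR called 0 genes for MUT and 10 for WT, or 13 and 0, so no shared gene could be seen. The r between the MUT fold changes of a batch and the WT fold changes of another batch, which share no libraries, ran from -0.13 to 0.045.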

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

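The comparison of other pairings of batch-and-medium sets and the tests on batch 2 were chosen after the gene counts were seen, and the re-dealing of labels within batches before.

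LHX1, a gene on the list of HEK293 markers, stood at 2.19 CPM in MUT library 3 of batch 3, where the other 9 MUT libraries ran from 0.0295 to 1.02. This was 1 of 291 groups of libraries with a value beyond Dixon's limit, where chance gives about 15. Each group held the libraries of a medium from all 3 batches, so gaps between batches could hide an outlying library. The chance number takes no account of such gaps, so the low count does not show that outlying libraries were few. The change between media differed between the batches for 9359 genes for MUT vs EV, 6046 for MUT vs WT and 5131 for WT vs EV, by the interaction test.

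The pooled gene counts were set against chance in 2 ways. With labels re-dealt among the libraries of each batch, 1 of 100 splits, the real one, gave as many genes as the 1106 for MUT vs EV (highest other 1) and 1 of 100 as many as the 188 for MUT vs WT (highest other 3), and 2 of 100 gave as many as the 67 for WT vs EV, where another split called 602 and so points to a structure among the libraries. Single libraries dealt by chance thus rarely gave counts of this size. Libraries of a batch and medium were correlated, at 0.43 in the voom fit, and re-dealing them singly breaks up these sets. The real labels could therefore give the most genes whether or not the medium matters, and re-dealing cannot decide that. With whole batch-and-medium sets of libraries kept together and paired otherwise, 41 of 108 pairings gave as many genes as MUT vs EV, 76 as many as MUT vs WT and 84 as many as WT vs EV, the highest other giving 4675. Differences between sets of libraries, whatever their medium, could therefore account for counts of this size, and an effect of the medium stays open beside them.

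Batch 2 called far more genes than batches 1 and 3, at 9843 against 294 and 10 for MUT vs EV. Greater depth as the cause is argued against, since with every library thinned to 26.2 M counts batch 2 still called 9225 genes and the others 349 and 11, with 117, 6255 and 234 in batches 1, 2 and 3 for MUT vs WT and 3, 7431 and 2 for WT vs EV. A GC content or gene length bias of single libraries as the whole cause is argued against by the 10580 genes called in batch 2 with those trends removed, against 68 and 31. For MUT vs WT the counts went from 58, 6815 and 248 in batches 1, 2 and 3 to 547, 6916 and 200, and for WT vs EV from 3, 8006 and 2 to 39, 8900 and 4, so these trends move the counts of batch 1 by many times. Closer agreement of the libraries of batch 2, whose median SD was 0.0985 against 0.124 and 0.118, may add to the count. As the whole cause it is argued against, since it would not widen the spread of fold changes over genes. Over all genes, the SD of log2 fold changes in batch 2 was 1.48 times that of the larger of the other batches for MUT vs EV. It was 1.23 times for MUT vs WT and 1.54 times for WT vs EV. These ratios lay on both sides of a limit of 1.5, which was set after the data were seen and so did not decide. Over genes above 5 CPM, a restriction chosen after seeing the values, the ratios were 2.06, 1.66 and 2.70. For MUT vs EV the SDs of these genes were 0.158, 0.353 and 0.171 in batches 1, 2 and 3. Media or cells handled differently in batch 2 were not tested and stay open, as does a stronger response to the media there.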

How the results depend on the processing

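The summed profiles, the fit with correlated libraries and the GC content and length offsets were chosen after seeing the data. For MUT vs EV, MUT vs WT and WT vs EV, against 1106, 188 and 67 genes, DESeq2 called 2168, 584 and 374, and the GC content and length offsets 1881, 419 and 234. No filter on low counts left 232 and 81 for the MUT comparisons, and the fit of only the 2 groups compared gave 20, 393 and 372. With no batch term edgeR called 0, 0 and 0 (unadjusted 1709, 894 and 801), against a fold of 1.2 0, 0 and 0 (unadjusted 562, 311 and 370), and with summed profiles 0, 0 and 0. Correlated libraries gave 1, 2 and 11, and voom with quality weights 1 for MUT vs EV. Batch 1 alone gave 294, 58 and 3, batch 2 alone 9843, 6815 and 8006, and batch 3 alone 10 for MUT vs EV and 2 for WT vs EV. Without batch 1 the counts were 104 for MUT vs WT and 29 for WT vs EV, without batch 2 0 for MUT vs EV (unadjusted 1916) and 305 for MUT vs WT, and without batch 3 4744, 1552 and 551. DESeq2 size factors, total library size and the stricter filter kept the 3 counts within 1.5 times. The cause was not tested where fewer samples or genes do not give it.

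The 62 genes that set MUT apart from both became 260 with DESeq2, 170 with GC content and length offsets, 12 with no filter, 9 with only the 2 groups, 33 without batch 1, 1054 without batch 3, 26, 4203 and 8 in batches 1, 2 and 3 alone, and 0 with no batch term, voom with quality weights, a fold of 1.2, summed profiles, correlated libraries or without batch 2. With EV split, MUT and WT called 0 and 10 genes, or 13 and 0, so the 18 genes shared by MUT and WT against EV could not be seen again.

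Leaving out single libraries moved counts by over 1.5 times. For MUT vs EV these ran from 5 to 1999: MUT batch 1 libraries 2 and 3 gave 305 and 661, EV batch 2 libraries 1, 2 and 3 gave 70, 5 and 6, MUT batch 2 libraries 1, 2 and 3 gave 5, 59 and 47, EV batch 3 library 3 gave 1757 and MUT batch 3 library 3 gave 1999. For MUT vs WT they ran from 63 to 123: WT batch 1 library 2 gave 81, WT batch 2 libraries 1, 2 and 3 gave 76, 95 and 87, MUT batch 2 libraries 1, 2 and 3 gave 63, 102 and 70, and WT batch 3 library 2 gave 123, while the highest count, 253 without MUT batch 3 library 3, stayed within 1.5 times. For WT vs EV they ran from 19 to 138: EV batch 1 library 3 gave 110, WT batch 1 library 1 116, EV batch 2 libraries 20, 19 and 21, WT batch 2 libraries 27, 34 and 36, EV batch 3 library 3 124 and WT batch 3 library 1 138. For MUT against both they ran from 2 to 135: WT batch 1 libraries 1 to 4 gave 34, 24, 38 and 41, MUT batch 1 library 2 26, EV batch 2 libraries 12, 2 and 2, WT batch 2 libraries 31, 37 and 29, MUT batch 2 libraries 2, 8 and 6, WT batch 3 library 2 36 and MUT batch 3 library 3 135.

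Replicate numbers are not stated to pair libraries. Same-numbered libraries of a batch deviated with correlations of -0.058 to 0.089, 0 of 28 pairs over 0.1, and 16 of 29 libraries correlated best with their own number. The median correlation was 0.0089, against -0.0048 for the 66 other pairs across media within a batch. How many best matches chance would give was not worked out, so a weak pairing stays open. With the replicate block in place of batch, edgeR called 0 genes for MUT vs EV (unadjusted 4495), 54 for MUT vs WT, 31 for WT vs EV and 0 for MUT against both, and camera 15, 18 and 15 lists.

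For lists, called 13, 18 and 16 times, the estimated correlation gave 0, 0 and 0 (unadjusted 5, 6 and 6), no batch term 4, 10 and 8, and without batch 2 8, 9 and 4. Fry gave 5 for MUT vs WT and 1 for WT vs EV, and without batch 1 gave 11 for MUT vs WT. Summed profiles gave 11, 13 and 13. The interaction counts stayed within 1.5 times under the stricter filter and DESeq2 size factors.

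Over 107 gene results and 5127 values, 3632 kept the call or its absence, 1443 lost the call, 36 gained it and 16 reversed. A change of sign counted as reversed only where the gene passed in the main fit or under the alternative. Where the gene passed in neither, the value counted among the 3632 whatever its sign. CEL for MUT vs EV, at -0.406 to 0.223, was such a case. In batch 3 alone, SSR1 was at -0.097, SEL1L -0.026, NEUROD1 -0.043, SMAD7 -0.129, TP53INP1 -0.069, SCD -0.089, MCL1 -0.109, SOX4 -0.050, DDB2 0.041, MCM7 0.031 and MCM5 0.098 for MUT vs EV, and AURKA -0.021 and CD24 -0.016 for MUT vs WT. In batch 1 alone TGFB1 was at -0.023 and BID at -0.013, and in batch 2 alone TXNIP at -0.234, for MUT vs EV. The cause was not tested.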

Other observations

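The tests of noncoding transcripts were chosen after the pattern was seen in the gene counts by class.

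Calls for MUT vs EV differed in direction by the class of the gene. Of 14704 protein-coding genes tested, 589 were higher and 326 lower, while of 3576 long noncoding and other genes 18 were higher and 89 lower, and of 960 pseudogenes 5 were higher and 28 lower. The median log2 fold change of the long noncoding class was -0.05, with -0.083, -0.068 and -0.012 in batches 1, 2 and 3, and that of pseudogenes -0.07, with -0.105, -0.09 and -0.01. For WT vs EV, 4 long noncoding genes were higher and 1 lower, with class medians of 0.02, -0.114 and 0.024 in batches 1, 2 and 3 and pseudogene medians of 0.006, -0.082 and 0.025. In batch 2 these classes thus lay lower in WT as well as in MUT. The tests that follow cover batches 1 and 2, where the medians lay farthest from 0.

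Low counts were weighed for this pattern. Against protein-coding genes matched on mean CPM, the median of noncoding genes and pseudogenes lay lower by -0.0527 in batch 1 (bootstrap range -0.0679 to -0.0406) and -0.0293 in batch 2 (-0.0528 to 0.00438), so low counts may explain part of it, and in batch 2 the share that remains cannot be told apart from 0. A GC content or gene length bias of single libraries as the whole cause is argued against, because the difference from all protein-coding genes stayed at -0.0681 in batch 1 and -0.0501 in batch 2 with those trends removed, from -0.103 and -0.0847 before. What lies behind the remaining difference was not tested.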
